A study of Rattus norvegicus with 8 samples.

How the data were processed

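RNA sequencing was done on glia cultured from the hippocampus of rats at postnatal day 0, per the labels' protocols. The cultures were kept in medium with 10% fetal bovine serum and used after 3 to 5 days in vitro, stained with Nile red and sorted by fluorescence. The labels give 4 samples with low and 4 samples with high lipid droplet content, and each sample was put in its group by its title. RNA was purified with a kit for small samples and cDNA was amplified with the Ovation RNA-seq v2 kit before library construction, per the labels' protocols, so that amplification is part of each level. The tools are Bowtie2 and Cuffdiff and the build is rn6, per the submitters' processing notes, with no versions stated. The gene annotation, the strand setting and any filter on reads are not given in the sources used here.

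The deposited gene tables list the genes that the authors called, 639 in a sheet of genes higher and 548 in a sheet of genes lower in LD-high glia, each marked as significant. For each gene the authors deposited 1 expression level per group, a log2 fold change, a p-value and a q-value, per the file headers. The headers name no unit for the levels. Cuffdiff reports FPKM, fragments per length of transcript and number of mapped fragments, and the levels are given here as FPKM on that ground, as the authors' pooled value per group. The smallest p-value that the authors deposited is 5e-05, which 348 genes share, and their q-value is 0.00187 for those genes. The number of per-sample columns is 0, so that levels of single replicates were not used here, no spread between replicates could be computed, no replicate could be left out and the depth of each sample is unknown. The precision of a level is therefore known only through the authors' p and q.

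The log2 change was computed from the 2 levels as LD-high over LD-low. It differed from the deposited log2 values by at most 1.15e-05, where those could be read. In the sheet of lower genes 20 cells of that column hold an error text of the spreadsheet, and these are the 20 genes listed at 0 in LD-high glia. A further 6 genes are listed at 0 in LD-low glia. A 0 in such a table can be a failed estimate, so no fold is given for these 26 genes. For the Benjamini-Hochberg adjustment, q times the rank of p over p gives the number of tests. That product lay between 12980.96 and 12981.04 at each of the 91 distinct p values, so 12981 genes were taken as tested and the 1187 listed genes as all genes with q below 0.05. A gene that is not among the called genes either did not pass or was not tested. Gene names and identifiers are those of the files, and 76 names are clone or provisional names, 1 name has been turned into a date and 4 rows have a repeated name. Coordinates are those of the deposited table in rn6, with starts raised by 1 because Cuffdiff writes them from 0. They are the locus that Cuffdiff reports, which can take in an overlapping neighbour. No genome sequence or annotation of that build was used, so exons and untranslated regions are not described.

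Before the data were examined, 25 lists of genes were fixed, 23 as written symbols and 2 (oxidative phosphorylation, cytosolic ribosomal proteins) as patterns of symbols, together with the tests and the rule for the genes named. No called gene belongs to more than 1 list. The rule names the 8 largest log2 changes in each direction among called genes with a symbol, a level above 0 in both groups and at least 1 FPKM in the higher group. It also names up to 4 called members of each list with the largest change, and 10 genes that the study's title and labels bear on (Plin2, Fasn, Cpt1a, Apoe, Gfap, Slc1a2, Slc1a3, Sod2, Gpx1 and Cat) whether called or not. Some genes that the rule takes are not reported here. Other members of the lists that are named were chosen after their values were seen. For each list with at least 3 called members, the called members higher and lower were compared with the other called genes by a two-sided Fisher's exact test and adjusted over the 13 such lists by the Benjamini-Hochberg method. Differences between sets of genes were tested with exact permutation tests or with 100000 permutations. For the myeloid and the detoxification list, the median change of the called members was also set against random sets of called higher genes. These were drawn in the same 10 classes of level, the level being the mean of both groups. This level-matched test was not part of the plan and was added once the direction of these lists was known. The calls themselves are those of the authors' test and no test of expression between samples was run. The plan had allowed for values per sample, which would have had a test of their own.

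The alternatives were q below 0.01, a log2 change of at least 1, a level of at least 1 or 5 FPKM in the higher group, leaving out genes at 0 in a group, leaving out repeated, clone or date names, a background of called genes outside all lists, leaving out genes of more than 1 list, and a p below 0.01 for the Gene Ontology terms. Comparison among genes with loci of similar length (5 classes with about equal numbers of genes), and comparison with all tested genes, were added after the data had been seen. The terms were deposited by the authors as lists with an identifier and a p-value per term, from the PANTHER overrepresentation test (release 20160715) with the Gene Ontology database of 2017-01-26, per the file headers. The lists name no genes, so terms were compared by identifier.

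The list test was tested on 200 simulated sets of directions for the 1187 called genes. With shuffled directions 2.77% of tests had an unadjusted p below 0.05. With 95% of its members set higher, the cell cycle list (26 called members) was recovered in 99.0% of the simulations and the neuron list (12 called members) in 56.5%, so that a list with few called members can miss the threshold even when nearly all of them are higher. The neuron markers were lower in the data, a direction that was not simulated. The level-matched test gave p below 0.05 for 5.5% of 200 random sets of 11 of the 633 higher genes above 0 in both groups, and for 97.0% of such sets once raised by 1 on the log2 scale. The number of tested genes was recovered correctly in 20 of 20 simulated tables. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.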

Results

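The samples were cultures of glia from the hippocampus of newborn rats (postnatal day 0), stained with Nile red, a dye that fluoresces in neutral lipid, and separated by fluorescence-activated cell sorting. Lipid droplets are the organelles in which cells store neutral lipid. RNA was sequenced from 4 samples of glia with few lipid droplets (LD-low) and 4 samples of glia with many (LD-high). The title of the study concerns metabolic coupling between neurons and astrocytes and the toxicity of fatty acids. The comparison asks which transcripts differ between droplet-poor and droplet-rich glia. The values used here are 1 level per gene and group with the authors' p and q. No spread between replicates and no depth per sample could be given, and no level below carries an SD or n. The labels number the samples of each group but do not say whether they came from separate animals or cultures. The authors' p-values then measure the spread between these samples, which may be technical.

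The genes with the largest increases in LD-high glia included immune receptors. Tlr13, a Toll-like receptor, rose from 0.992 to 27.6 FPKM (log2 change 4.80, q = 0.00187) in the authors' deposited table. Cd180, a relative of the Toll-like receptors, rose from 3.22 to 80.7 FPKM there (log2 change 4.65, q = 0.00187). The largest decreases included genes of neurons. Neurod1, a transcription factor of neuronal differentiation, fell from 56.4 to 1.49 FPKM (log2 change -5.25, q = 0.00187) in the authors' deposited table. Dcx, a microtubule protein of young neurons, fell from 99.7 to 3.39 FPKM there (log2 change -4.88, q = 0.00187). The authors' deposited table called 1187 genes, of which 639 were higher and 548 lower in LD-high glia. These were 4.92% and 4.22% of the 12981 genes that the authors had tested, a number recovered from their p and q values. The median log2 change was 1.13 among higher genes and -1.40 among lower genes, leaving out 26 genes listed at 0 in 1 group. Of the genes above 0 in both groups, 402 higher and 407 lower genes differed by more than 2-fold in the authors' deposited table. The number of called genes depends on the threshold: at q below 0.01 there were 297 higher and 257 lower genes.

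Tlr13 (ENSRNOG00000061403) lies at chromosome X, 77212458 to 77234046, in the rn6 build, and Cd180 (ENSRNOG00000010266) at chromosome 2, 32820322 to 32833125. Neurod1 (ENSRNOG00000005609) lies at chromosome 3, 66403184 to 66436668, and Dcx (ENSRNOG00000047712) at chromosome X, 115098675 to 115175299. Other genes among the 8 largest increases in the authors' deposited table were Afap1l1 (log2 change 4.59), Pik3cg, a phosphoinositide kinase of leukocytes (4.43), Cd53, a leukocyte tetraspanin (4.41), Trim55 (4.35) and Rgs1, a regulator of G protein signalling (4.29). The other large decreases in the authors' deposited table were Cacna1b, the pore subunit of the N-type calcium channel (log2 change -5.15), Celsr3, a cadherin of axon guidance (-5.02), Ina, a neuronal intermediate filament (-4.82), Chgb, a secretory granule protein (-4.76), Psd (-4.64) and Mapt, which encodes tau (-4.48). Their q in the authors' deposited table was at most 0.0179.

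Lists of genes for lipid handling, oxidative stress, cell types and other processes had been fixed before the data were examined. For each of the 13 lists with at least 3 called members, the split between higher and lower members was set against that of the other called genes with a two-sided Fisher's exact test, adjusted over the 13 lists (Benjamini-Hochberg). The genes are not independent replicates, so this p describes the split and not the spread between samples. 6 lists passed an adjusted p of 0.05. In each of the 13 lists all called members lay on 1 side, so the p depended only on their direction and number. With 3 members higher the unadjusted p was 0.254, and with 5 higher it was 0.0657 (Fisher's exact test). Such lists could not pass, and their p does not argue against a shared direction.

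Markers of microglia and macrophages, the immune cells of the brain, were higher in LD-high glia. Of 29 symbols, 13 were called in the authors' deposited table and all 13 were higher (adjusted p = 0.00148, Fisher's exact test). Their median log2 change was 3.47, with a range from 2.20 to 4.41. Aif1, which encodes the microglial protein Iba1 (ENSRNOG00000000853, chromosome 20, 5161333 to 5166448), rose from 5.31 to 71.1 FPKM (q = 0.00187) in the authors' deposited table. Fcer1g, a signalling chain of immune receptors, rose from 16.8 to 235 FPKM in the authors' deposited table, the highest level among the called members in LD-high glia. Ptprc, the leukocyte antigen CD45, rose from 0.735 to 10.6 FPKM in the authors' deposited table. Csf1r, the receptor that microglia need to survive, rose from 2.98 to 30.7 FPKM, and Trem2, a lipid-sensing receptor of microglia, from 2.56 to 18.6 FPKM in the authors' deposited table.

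Neuron markers were lower in LD-high glia. Of 23 symbols, 12 were called in the authors' deposited table, 0 higher and 12 lower (adjusted p = 0.000571, Fisher's exact test). Their median log2 change was -3.32, with a range from -4.88 to -0.84. Tubb3, a neuronal tubulin, fell from 30.9 to 1.54 FPKM and Nefl, the neurofilament light chain, from 4.83 to 0.268 FPKM in the authors' deposited table. Snap25, a protein of synaptic vesicle release, fell from 74.2 to 9.11 FPKM, and Map2, a dendritic microtubule protein, from 161 to 80.7 FPKM in the authors' deposited table.

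**Figure D1:**
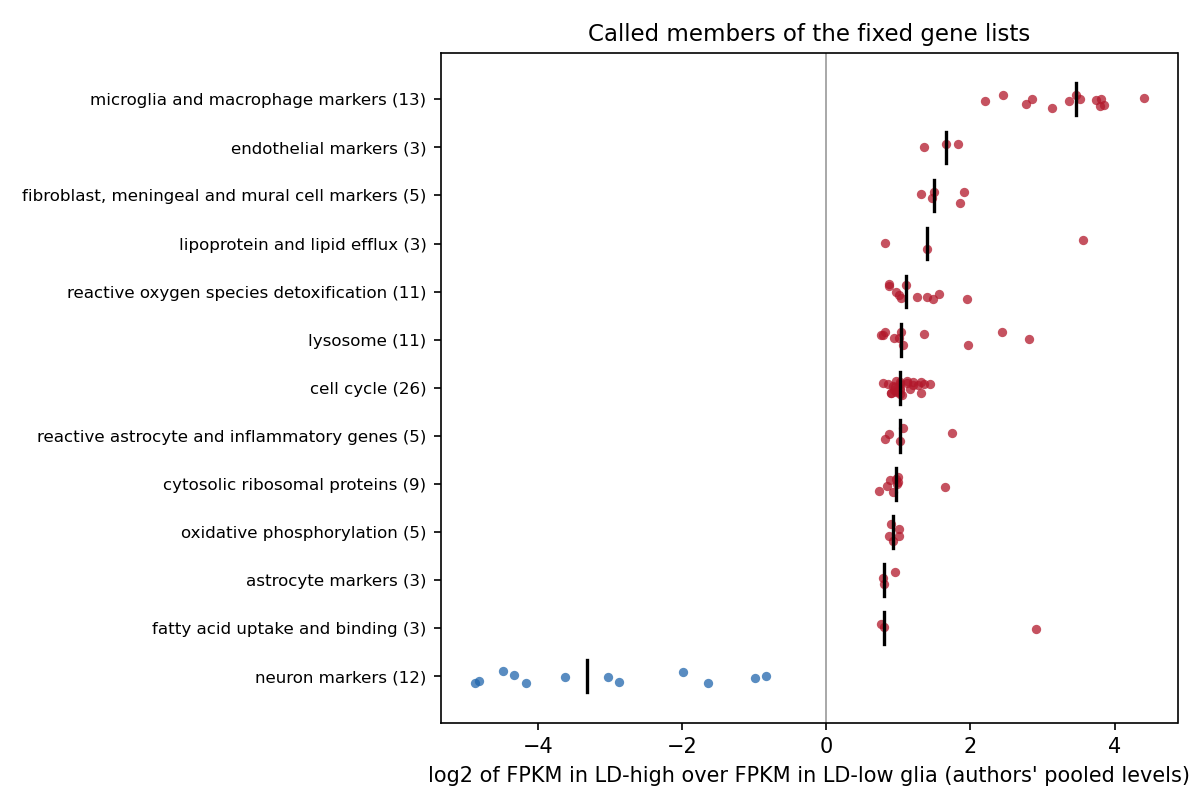
Log2 of the level (FPKM) in LD-high over LD-low glia for each called member of the 13 lists with at least 3 called members, from the authors' pooled levels. Each point is a gene, red if higher and blue if lower in LD-high glia, the number of called members stands beside each list, and the black bars mark the medians, which are 3.47 for microglia and macrophage markers and -3.32 for neuron markers.

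The lists for other cell types had at most 5 called members each. Astrocytes, the main glial type that such cultures are grown for, had 3 of 22 marker symbols called in the authors' deposited table, all 3 higher, with a median log2 change of 0.80. They were Acsbg1, an acyl-CoA synthetase (13.4 to 25.9 FPKM), the zinc transporter Slc39a12 (19.2 to 33.5 FPKM) and the bicarbonate transporter Slc4a4 (16.4 to 28.1 FPKM). The split of this list had an adjusted p of 0.254 (Fisher's exact test), but a list with 3 called members, all higher, could not pass. Gfap, the astrocyte intermediate filament, and the glutamate transporters Slc1a2 and Slc1a3 were not among the called genes. Fibroblast, meningeal and mural cell markers had 5 called members of 21 symbols in the authors' deposited table, 5 higher and 0 lower (adjusted p = 0.0948, Fisher's exact test). Among them were the collagen genes Col1a1 (39.8 to 113 FPKM) and Col3a1 (12.3 to 33.9 FPKM), the matrix protein gene Postn (14.6 to 55.0 FPKM) and Rgs5 (4.52 to 16.4 FPKM). With only changes of at least 1 on the log2 scale counted, the adjusted p of this list was 0.0367. Against all tested genes, a comparison added after the data were seen in which each symbol was taken as tested, its adjusted p was 0.0230 (one-sided Fisher's exact test). Endothelial markers had 3 called members of 12 symbols in the authors' deposited table, Esam, Eng and Flt1, all 3 higher with log2 changes from 1.36 to 1.83 (adjusted p = 0.254, Fisher's exact test, and 0.0957 against all tested genes). Of 17 oligodendrocyte lineage symbols 2 were called, and both were lower. They were Pdgfra, a receptor of oligodendrocyte precursors (5.21 to 1.03 FPKM), and Bcas1 (20.7 to 3.37 FPKM) in the authors' deposited table. Of 13 ependymal and choroid plexus symbols 1 was called, the axonemal dynein gene Dnah9, which was lower (2.06 to 0.981 FPKM) in the authors' deposited table.

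Genes for the detoxification of reactive oxygen species were higher in LD-high glia. Of 46 symbols, 11 were called in the authors' deposited table and all 11 were higher (adjusted p = 0.00325, Fisher's exact test). Their median log2 change was 1.11, with a range from 0.87 to 1.95. Cat, which encodes catalase, the enzyme that breaks down hydrogen peroxide (ENSRNOG00000008364, chromosome 3, 93379874 to 93412058), rose from 119 to 315 FPKM (log2 change 1.40, q = 0.00187) in the authors' deposited table and had the highest level among the called members. Gpx3, a secreted glutathione peroxidase, rose from 2.87 to 11.1 FPKM and Sod3, the extracellular superoxide dismutase, from 17.9 to 53.1 FPKM in the authors' deposited table. Hmox1, which degrades haem, rose from 14.7 to 41.2 FPKM in the authors' deposited table. Sod1 (78.1 to 156 FPKM), Gclc, an enzyme of glutathione synthesis (90.3 to 176 FPKM), and Nfe2l2, the transcription factor NRF2 (49.3 to 89.9 FPKM), were also higher in the authors' deposited table, as were Slc7a11, Gstp1 and Gpx8. Txnip, also counted among the 11, encodes an inhibitor of thioredoxin and not a detoxifying enzyme. It was higher too (12.3 to 22.7 FPKM in the authors' deposited table). Sod2 and Gpx1 were not among the called genes. In the same comparison 13 myeloid markers, 5 fibroblast, meningeal and mural markers (median log2 change 1.501) and 3 endothelial markers (1.66) were higher and 12 neuron markers were lower.

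Lysosomal genes were higher as well. Of 32 symbols, 11 were called in the authors' deposited table, all 11 higher (adjusted p = 0.00325, Fisher's exact test), with a median log2 change of 1.04. Gpnmb, a glycoprotein of lysosomes and macrophages, rose from 33.1 to 233 FPKM and the protease gene Ctsz from 1.96 to 10.6 FPKM in the authors' deposited table. The protease gene Ctsl rose from 52.9 to 135 FPKM in the authors' deposited table. These genes moved in the same direction as the 13 myeloid, 5 fibroblast, meningeal and mural and 3 endothelial markers, and at q below 0.01 the adjusted p of the list was 0.103.

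Few genes of lipid handling were called, and no lipid list passed in the comparison with all tested genes. The genes called from the lists for the droplet coat, lipolysis, uptake and efflux were higher in LD-high glia. Those called from the lists for fatty acid and cholesterol synthesis were lower. Plin2, the main coat protein of lipid droplets in most cells (ENSRNOG00000007060, chromosome 5, 104984414 to 105010857), rose from 12.4 to 31.8 FPKM (log2 change 1.36, q = 0.00187) in the authors' deposited table. It was the 1 called gene of 18 symbols for the droplet coat and droplet formation. Of 9 lipolysis symbols 2 were called, both higher in the authors' deposited table: Lipa, the lysosomal acid lipase (12.5 to 31.3 FPKM), and Abhd6 (9.39 to 21.7 FPKM). Fatty acid uptake and binding had 3 called members of 14 symbols, all 3 higher in the authors' deposited table (adjusted p = 0.254, Fisher's exact test). They were Lpl, lipoprotein lipase (2.62 to 19.7 FPKM), and the fatty acid binding protein genes Fabp7 (1588 to 2759 FPKM) and Fabp5 (253 to 428 FPKM). Lipid efflux had 3 called members of 12 symbols, all 3 higher in the authors' deposited table (adjusted p = 0.254, Fisher's exact test). They were Apoe, the main apolipoprotein of the brain (111 to 292 FPKM, q = 0.00187), and the lipid exporters Abcg1 (0.324 to 3.84 FPKM) and Abca1 (24.1 to 42.5 FPKM). Fasn, fatty acid synthase (17.3 to 10.4 FPKM, q = 0.0351), and Acaca, acetyl-CoA carboxylase (8.12 to 4.02 FPKM, q = 0.0214), were lower in the authors' deposited table. They were the 2 called genes of 19 symbols for fatty acid synthesis. Of 24 cholesterol synthesis symbols 1 was called, Lss, which was lower (27.5 to 15.2 FPKM) in the authors' deposited table. Of 37 symbols for fatty acid oxidation 1 was called, Etfa, an electron transfer protein, which was higher (13.8 to 29.6 FPKM) in the authors' deposited table. Cpt1a, which controls the entry of fatty acids into mitochondria, was not among the called genes. No member of the list for triglyceride synthesis (22 symbols) was called. The lipid lists with fewer than 3 called members were not tested for direction. The comparison with all tested genes was added after the data were seen. For higher members its adjusted p was 0.289 for lipolysis, 0.132 for uptake and 0.0957 for efflux (one-sided Fisher's exact test). For lower members it was 0.625 for fatty acid synthesis (same test). Of the droplet coat symbols 5.56% were called higher, beside 4.92% of all tested genes. Of the cholesterol synthesis symbols 4.17% were called lower, beside 4.22% of all tested genes. The lipid genes that were higher moved in the same direction as the 13 myeloid, 5 fibroblast, meningeal and mural and 3 endothelial markers. Fasn, Acaca and Lss moved in the same direction as the 12 neuron markers (median log2 change -3.32) and the 2 oligodendrocyte lineage markers (-2.48).

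Cell cycle genes formed the list with the most called members. Of 74 symbols, 26 were called in the authors' deposited table, 26 higher and 0 lower in LD-high glia (adjusted p = 1.62e-06, Fisher's exact test). Their median log2 change was 1.02, with a range from 0.79 to 1.44. Kif20b, a mitotic kinesin, rose from 6.81 to 18.4 FPKM and Cenpe, a kinetochore motor, from 26.2 to 65.1 FPKM in the authors' deposited table. Smc4, a condensin subunit, rose from 24.2 to 60.2 FPKM in the authors' deposited table. Esco2, an acetyltransferase of cohesin, rose from 5.41 to 13.8 FPKM in the authors' deposited table. That table also lists pseudogenes of Esco2, so its level is uncertain. In the same comparison 13 myeloid, 5 fibroblast, meningeal and mural (median log2 change 1.501) and 3 endothelial markers (1.66) were higher and 12 neuron markers lower.

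**Figure D2:**
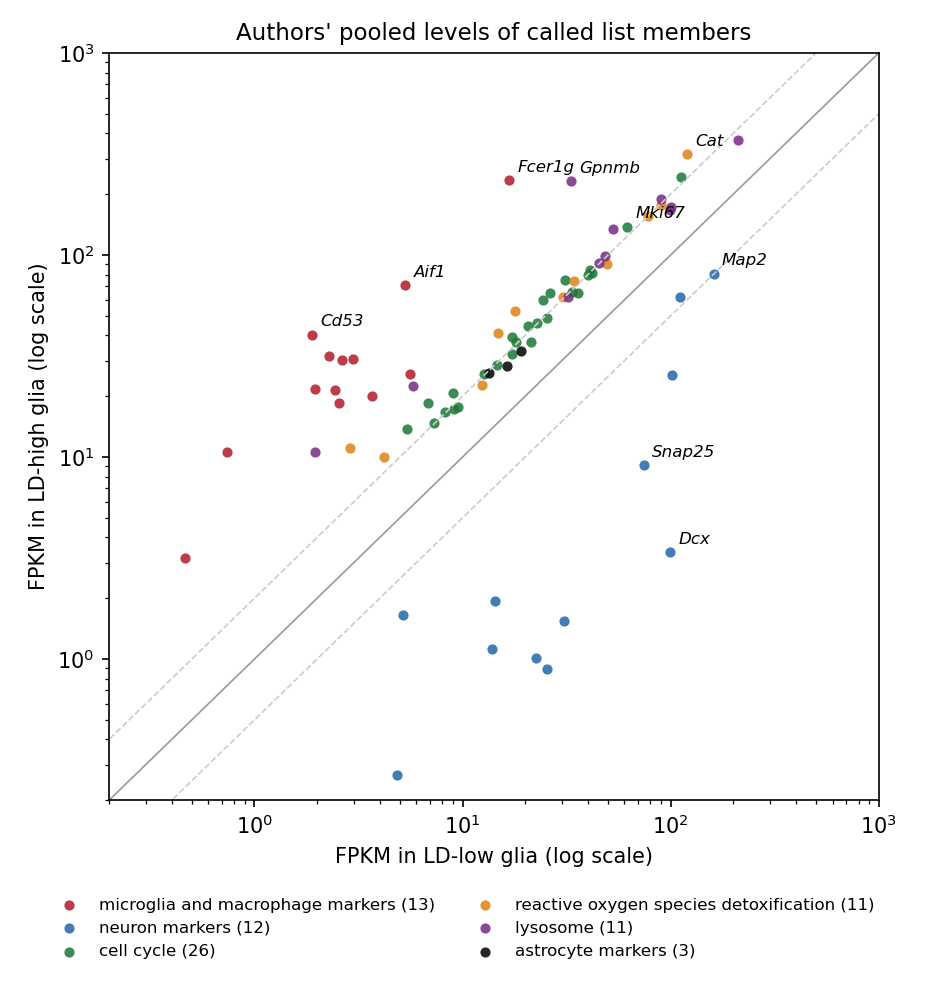
Level (FPKM, log scale) in LD-high glia against LD-low glia for the called members of 6 lists, from the authors' pooled levels, with 1 point per gene and the number of called members in the key. The solid line marks equal levels and the dashed lines a 2-fold difference; the 13 microglia and macrophage markers lie more than 2-fold above the line of equal levels and the 12 neuron markers lie below it.

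Cytosolic ribosomal protein genes had 9 called members in the authors' deposited table, 9 higher and 0 lower (adjusted p = 0.010, Fisher's exact test), with a median log2 change of 0.97. Rpl39 rose from 57.9 to 181 FPKM, Rps24 from 99.5 to 199 FPKM, Rpl24 from 70.2 to 140 FPKM and Rpl23 from 68.9 to 136 FPKM in the authors' deposited table. Genes of this family have many near-identical copies among which reads can be split, which makes their levels uncertain. The called loci of Rpl30, Rps15al4, Rpl31l4 and Rps13 span only 0.434 to 0.523 kb, and the others at least 2.96 kb. Whether the short loci are such copies was not tested. The adjusted p of the list was 0.253 at q below 0.01 and 0.0614 when directions were compared only among genes with loci of similar length. Oxidative phosphorylation genes had 5 called members in the authors' deposited table, Atp5l, Uqcrq, Cox6c, Atp5g3 and Cycs, all 5 higher with log2 changes from 0.87 to 1.01 (adjusted p = 0.0948, Fisher's exact test). Genes of reactive astrocytes and inflammation had 5 called members of 29 symbols in the authors' deposited table, all 5 higher (adjusted p = 0.0948, Fisher's exact test). Among them were Ptgs2, a cyclooxygenase (1.99 to 6.66 FPKM), Vcam1, an adhesion molecule (11.8 to 24.6 FPKM), and the chemokine gene Ccl2 (44.5 to 90.3 FPKM) in the authors' deposited table. Of 22 symbols for glycolysis 1 was called, Hk1, a hexokinase, which was lower (20.04 to 10.1 FPKM) in the authors' deposited table. Of 15 hypoxia-response symbols 2 were called, 1 higher and 1 lower, and Mxi1 was the lower one (20.8 to 8.56 FPKM) in the authors' deposited table. Of 25 immediate early symbols Egr3 was higher (1.78 to 6.59 FPKM) and Nr4a3 lower (7.64 to 2.59 FPKM) in the authors' deposited table. The ribosomal, oxidative phosphorylation and inflammatory genes moved in the same direction as the 13 myeloid, 5 fibroblast, meningeal and mural and 3 endothelial markers, while 12 neuron markers were lower. The 4 called genes of the mitochondrial genome were also higher, by 2.17-fold to 3.57-fold in the authors' deposited table. No member of the list for endoplasmic reticulum stress (18 symbols) was called.

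The authors' deposited lists of Gene Ontology terms held 227 terms for the genes higher in LD-high glia and 104 for the genes lower in LD-high glia, with 37 terms in both lists. Terms of the nervous system led among the lower genes, with nervous system development at p = 6.42e-29 and generation of neurons at p = 3.35e-24 in the authors' deposited table. Nervous system development is 1 of the 37 shared terms and had p = 0.0474 for the higher genes in the authors' deposited table. The string neuro was part of 19 term names for lower genes. Among the higher genes, immune system process had p = 6.79e-11, response to oxidative stress p = 1.94e-07, response to lipid p = 1.56e-07 and mitotic cell cycle p = 7.52e-07 in the authors' deposited table. In that list 16 term names contain immun, 4 name oxidative stress, reactive oxygen species or hydrogen peroxide, and 19 name the cell cycle or a step of mitosis. The word lipid was part of 2 names, response to lipid and cellular response to lipid, and 0 names held fatty acid, lipid metabolic or lipid storage. Terms for oxidative stress and for the cell cycle were found by name in the list for higher genes and in 0 names of the list for lower genes. The authors' deposited table gives a p for each term after Bonferroni correction for 8341 terms but does not say whether a term was over- or underrepresented. Chemical stimulus, smell or sensory perception is part of 5 names for higher and 3 names for lower genes. The counts of terms may therefore mix over- and underrepresented terms. A p below 0.01 was given for 172 terms of higher genes and 89 of lower genes. The reference for these tests was all rat genes of the database and not the genes that could have been called, so a term can be listed because its genes are expressed in such cultures at all.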

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

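The comparison within 5 classes of locus length and that with all tested genes were chosen after the data were seen, and the other alternatives before. At q below 0.01 the counts came to 297 higher and 257 lower genes, and at a log2 change of at least 1 to 408 higher genes, with genes at 0 in LD-low glia counted as changed, because fewer genes pass a stricter limit. Genes higher in LD-high glia made up 53.8% of the called genes, and between 48.9% (log2 change of at least 1) and 56.2% (at least 5 FPKM) under the alternatives. The lysosome list had an adjusted p of 0.103 at q below 0.01, where 5 members are left, and the ribosomal list 0.253, where 3 are left. Within the 5 classes of locus length the ribosomal list had 0.0614. Its 9 called loci all lie in the class of the shortest loci, where 65.1% of the called genes were higher. Why short loci were more often higher was not tested. The fibroblast, meningeal and mural list had 0.0367 at a log2 change of at least 1. There its 5 members are set against fewer lower and higher genes, of which a smaller share is higher, and the adjustment covers 8 lists in place of 13. No list could change direction, because all called members of each tested list lay on 1 side, so this says nothing about stability. The adjusted p lay between 3.91e-07 and 0.000336 for the cell cycle, 0.000328 and 0.00862 for microglia and macrophages, 0.000475 and 0.00505 for neurons, and 0.00246 and 0.0335 for detoxification, over 5 alternatives each. A level of at least 1 FPKM and leaving out genes of more than 1 list removed no called gene and say nothing about stability. Against all tested genes the adjusted p of the fibroblast, meningeal and mural list was 0.0230. No paired analysis was possible because the levels used here are pooled per group and carry no replicate number. For the same reason the alternatives of leaving out a replicate, of another normalization and of another pseudocount were not run, and the term-size alternative was not run because the term lists give no genes. Depth is unknown, and a gene that was not called either did not pass or was not tested.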

Other observations

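The tests of gene families, short loci and locus length, of the shares of the myeloid and neuron lists that were called, and of the change of the detoxification genes beside that of the myeloid markers were chosen after their results had been seen. Among families of genes with a shared symbol stem and at least 5 called members, 15 in all, the voltage-gated calcium channel genes named Cacna had 6 called members, all 6 lower in LD-high glia (Fisher's exact test, adjusted p = 0.0864 over the 15 families), and 0 families passed 0.05. In the authors' deposited table Cacna1h, of a low-voltage channel, fell from 2.75 to 0.421 FPKM and Cacna1a, of the P/Q-type channel, from 2.44 to 0.642 FPKM. Of 11 genes whose symbols begin with Cd and a number, 10 were higher (Fisher's exact test, adjusted p = 0.0864). Cd200, a ligand that restrains myeloid cells, fell from 15.7 to 1.61 FPKM in the authors' deposited table. These genes, Cd2ap among them, were grouped by symbol only and need not be related.

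The 4 called genes of the mitochondrial genome, Mt-nd1, Mt-nd2, Mt-nd4 and Mt-co2, were all higher, and Mt-nd1 went from 4957 to 13169 FPKM in the authors' deposited table (q = 0.0351). Among the called genes the highest level belonged to AABR07046778.1, a provisional gene of 0.267 kb on chromosome 5 (6373583 to 6373849), at 6228 FPKM in LD-low and 24587 FPKM in LD-high glia in the authors' deposited table. The 5 genes with the largest gains, this gene, 3 mitochondrial genes and RGD1563581, held 55.2% of the summed gain in FPKM of the 639 higher genes. Of 19 called loci under 500 bp, 15 were higher (Fisher's exact test, unadjusted p = 0.0349), and the median level in the higher group was 557 FPKM in these loci and 18.8 FPKM in the others. Hmgn1, a chromatin protein gene that most cells express, is listed at 0 in LD-high and at 3.41 FPKM in LD-low glia in the authors' deposited table. Lower genes had longer loci than higher genes, with medians of 40.3 and 26.02 kb (two-sided permutation test, p = 2e-05, the smallest that this two-sided test can give with 100000 permutations), and the share of higher genes was 65.1% in the class of the shortest loci and 35.7% in that of the longest, of 5 classes with about equal numbers of genes.

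Of 29 myeloid markers, the 13 called ones were higher, with a median log2 change of 3.47. A lower share of neurons in the LD-high sort is argued against as the whole cause. Random sets of called higher genes of similar level, which passed the same call, had a median of 1.20 (95% of sets between 1.00 and 1.51). The two-sided permutation p was 2e-05, the smallest the test can give. Like each permutation p given here, it was drawn over genes, which are not independent replicates. It does not measure the spread between samples. Sets matched on the level in LD-low glia alone had a median of 1.91. Genes that neurons also express would rise less, and the sets can hold such genes, so fewer neurons may still add to the rise. Of 22 astrocyte markers, the 3 called ones rose by 0.78 to 0.95 on the log2 scale, and the 2 called oligodendrocyte lineage markers fell. A larger share of microglia or macrophages in the LD-high sort stays open and cannot be told apart from higher expression within cells: that 44.8% of the list was called higher is the pattern itself, with Fcer1g at 235 FPKM and Aif1 at 71.1 FPKM in LD-high glia, and speaks for neither. The labels name a gate on Nile red and none that would remove these cells. Whether microglia held more droplets than other glia was not tested.

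Of 23 neuron markers, the 12 called ones were lower, with a median log2 change of -3.32. A bias against genes with long loci in the LD-high libraries is argued against as the whole cause, since the direction of the list had a permutation p of 0.00029 when directions were shuffled among called genes of the same class of locus length, of 5. Locus length takes in introns, so a bias against long transcripts was not tested. A larger share of neurons in the LD-low sort stays open and cannot be told apart from lower expression within cells, because pooled levels do not count cells. That 52.2% of the list was called lower, with Map2 at 161 FPKM and Stmn2 at 102 FPKM in LD-low glia, is the pattern itself and speaks for neither.

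Of 46 detoxification symbols, the 11 called ones, catalase among them, were higher with a median log2 change of 1.11, beside 3.47 for the 13 called myeloid markers, 1.501 for the 5 called fibroblast, meningeal and mural markers and 1.66 for the 3 called endothelial markers. A lower share of neurons in the LD-high sort stays open. Random sets of called higher genes of similar level had a median of 1.02 (95% of sets between 0.88 and 1.35, two-sided permutation p = 0.4), and since all of these genes had to pass the same call, this likeness does not decide it. A larger share of microglia in the LD-high sort cannot be told apart from a change within the droplet-rich glia, since both myeloid and other glia express these genes and levels are pooled. That droplet-rich glia themselves express more catalase and related enzymes is a hypothesis that stays open and was not tested.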
